A study of Mus musculus with 11 samples.

How the data were processed

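Gene expression was measured in dendritic cells sorted from mouse spleen. There were 11 arrays, 6 from naive C57BL/6 mice and 5 from mice carrying transferred Eµ-Myc lymphoma cells, a transgenic B cell lymphoma driven by Myc. Per the labels, cells positive for CD11c and MHC class II were sorted to a purity above 95%, and tumour cells made up on average 10 to 36% of the lymphocytes in the lymphoma spleens. Total RNA was amplified and biotin-labelled with a whole-transcript kit and hybridised to a 1-colour Affymetrix mouse gene array, with 1 array per sample. The labels do not say whether each array came from its own mouse, so all p-values measure the spread between these 11 samples.

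The deposited values are log2 expression, 1 value per probeset and array, made by the authors with RMA. That method corrects background, normalises between arrays and summarises the probes of each transcript. Its version was not stated, nor why 7329 of the 41801 listed probesets are blank on every array. The other 34472 probesets were used. Array medians lay between 5.53 and 5.61 and 75th percentiles between 7.43 and 7.54, and the correlation between any 2 arrays lay between 0.989 and 0.996. For arrays, the number of arrays limits the precision.

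Probesets were named with the given probe table, which names 1 gene for 23521 probesets and several genes for 1814. Another 9137 had no named gene. Older symbols were matched through the given gene tables, one of which follows the GRCm38.p6 assembly. The files name no genome build, so no coordinates are given. Probesets with 1 gene entered the test, and of the 1082 genes with more than 1 probeset the one with the highest mean over all arrays was used, which left 22180 genes. No dim gene was removed. The 1105 olfactory receptor genes, not expected in these cells, had a median level of 3.40, and their 95th percentile of 5.60 served as a mark for dim genes.

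Differences were computed as exposed minus naive with limma 3.58.1 (lmFit, eBayes with trend = TRUE) in R 4.3.3. Genes counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. SE is limma's moderated standard error, and SD is the spread between the arrays of a group. Because each group has fewer than 10 arrays, single comparisons outside limma used exact permutation tests, two-sided, over all 462 ways to divide 11 arrays into 6 and 5. The smallest p these can give is 0.00216.

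Altogether 38 sets were fixed from general knowledge, 29 gene lists and 9 families found by a symbol pattern. Each was tested with camera, which asks whether its genes shifted relative to all other genes, with a preset inter-gene correlation of 0.01 and adjustment over the 38 sets. Camera with an estimated correlation, fry, and the exact permutation test of the set's mean were run beside it. A set's level is the mean of its members on an array. Named genes follow a rule: the 15 largest rises and 15 largest falls among changed genes, without predicted genes, small RNA genes, olfactory receptors and antigen receptor segments; the C/EBP family; up to 3 changed members of each set in each direction, or the member with the largest difference where none changed; and Itgax, Cd79a, Ms4a1, Cd3e and Myc as checks of the sort. The test, the sets, the naming rule and most alternatives were chosen before the data were examined.

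The last exposed array carries the number 6 in its title and 5 in another field. The numbers were not used to pair arrays. After removing group means, the correlation between naive and exposed arrays of the same number lay between 0.0880 and 0.231. Only 2 of the 5 exposed arrays correlated best with the naive array of their own number. Arrays numbered 1 to 3 did stand apart from those numbered 4 to 6 in both groups, which the labels do not explain, so values with this number set as a block and within each number set are given as well.

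Alternatives were limma without trend, with robust fitting, with array weights and with treat against a 1.2-fold change; median centring, another quantile normalisation and a shift to a common 75th percentile; filters on dim genes; the mean of a gene's probesets, and every probeset by itself; each replicate number as a block; the mean of the B cell or the red pulp macrophage markers as a covariate; and each array left out in turn. The number set as a block and each number set alone were added after the arrays had been seen. On simulated data of 22180 genes in the same design, with 200 genes changed, limma recovered 98% of 100 genes changed 2-fold and 86% of 100 genes changed by 0.5 on the log2 scale, 9 of its 193 calls were false, and camera called 0 unchanged sets. The simulated genes varied independently of each other. The simulation therefore does not test camera on sets whose genes vary together, such as the cell cycle list here (estimated correlation 0.59).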

Results

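Expression was profiled in CD11c- and MHC class II-positive dendritic cells from the spleens of naive mice (6 arrays) and of mice with Eµ-Myc lymphoma (5 arrays), to find which genes change in dendritic cells exposed to lymphoma. Values are log2 expression. Genes of the sort markers were high on both sides, which the sort itself nearly forces. Itgax, which encodes the CD11c used for sorting, was measured at 12.11 ± 0.08 (SD, n = 6) in naive and 11.98 ± 0.13 (SD, n = 5) in exposed cells. The 13 measured MHC class II presentation genes averaged 11.62 and 11.55. Markers not used to sort averaged 10.89 and 10.91 for type 1 and 9.57 and 9.46 for type 2 conventional dendritic cells. Checks for other lymphocytes did not pass the test. The B cell genes Cd79a and Ms4a1 differed by 0.36 (adjusted p = 0.452) and -0.21 (adjusted p = 0.506), the T cell gene Cd3e by 0.25 (adjusted p = 0.256) and Myc itself by 0.13 (adjusted p = 0.759). Cd3e alone moved past the threshold when 1 array was left out, at 0.34 (adjusted p = 0.0419) without exposed array 4.

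The first principal component held 24.6% of the variance and the second 16.6%. Arrays numbered 1 to 3 and arrays numbered 4 to 6 formed different sets in both groups, and 731 genes differed between the number sets, 146 higher in 1 to 3 and 585 higher in 4 to 6. Once group means were removed, the mean correlation between a naive and an exposed array was 0.127 within a number set (15 pairs) and -0.127 across sets (15 pairs). The sets hold 3 naive and 3 exposed arrays, and 3 naive and 2 exposed arrays, so group and number set are not confounded.

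**Figure D1:**
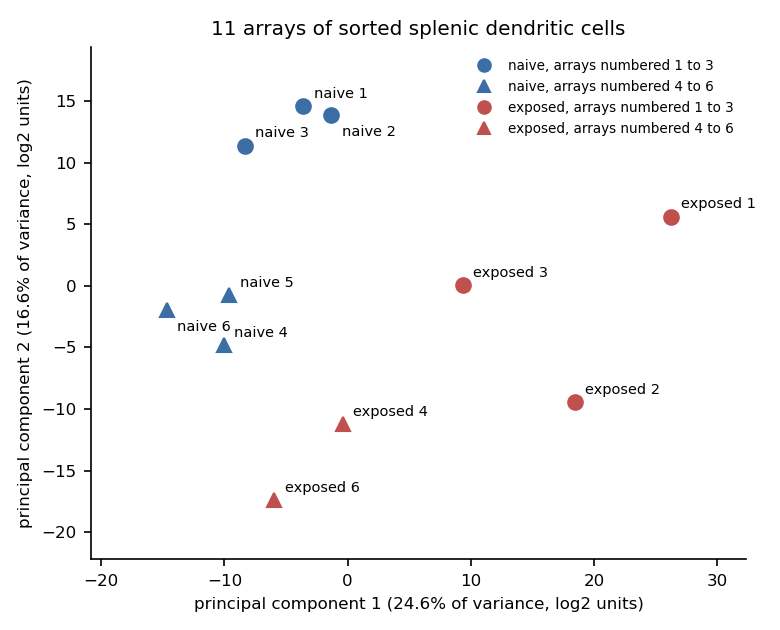
Positions of the 11 arrays on the first and second principal components (axes in component units), coloured by group, with circles for arrays numbered 1 to 3 and triangles for arrays numbered 4 to 6. Exposed arrays 1 and 2 lie farthest along the first component, at 26.2 and 18.4.

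Between exposed and naive cells, Clec4e, Fpr2 and Il6 showed the largest rises of the named genes and Il1r2, Mmp9 and Cyp4f37 the largest falls. Clec4e, the C-type lectin Mincle, a receptor for glycolipids, rose 3.85-fold, from 5.10 ± 0.31 (SD, n = 6) to 7.05 ± 0.90 (SD, n = 5; probeset 17470627), and Il6 rose 3.07-fold, from 5.54 ± 0.40 to 7.16 ± 0.40 (probeset 17435725). Il1r2, which binds interleukin 1 without signalling, was 3.38-fold lower, at 11.38 ± 0.33 in naive and 9.63 ± 0.86 in exposed cells (probeset 17212174). In all, 316 of 22180 genes changed (1.42%), 195 higher and 121 lower, and 22 of them by at least 2-fold, 15 higher and 7 lower. The median absolute log2 change of the 316 genes was 0.46. At an unadjusted p under 0.05 there were 2710 genes where chance gives 1109. Exposed and naive arrays did not overlap for 263 of the 316 genes, and for 2.29% of all tested genes, where chance gives 0.433%.

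With the number set as a block, 617 genes changed, 365 higher and 252 lower, among them all 316. All 316 had the same sign within each number set, which their selection on these same arrays nearly forces. Tested alone, arrays 1 to 3 gave 11 passing genes and arrays 4 to 6 gave 5. A limma interaction term between group and number set passed for 0 genes, with 943 at an unadjusted p under 0.05. The count of 316 moved with single arrays: it was 104 without exposed array 2, 165 without naive array 1, 177 without naive 2, 170 without naive 3, 155 without naive 5, 155 without naive 6 and 205 without exposed 3. The 2-fold count rose to 38 without exposed array 6. A shift of every array to a common 75th percentile gave 166 higher and 215 lower genes, 43.6% higher against 61.7% in the values as deposited. The other rescalings left more rises than falls, with 179 and 99 after median centring and 195 and 146 after quantile normalisation.

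The next largest rises included surface receptors. Fpr2, a receptor for formyl peptides, rose by 1.66 ± 0.22 (SE; adjusted p = 0.00409), Marco, a scavenger receptor of macrophages, by 1.54 ± 0.23 (adjusted p = 0.00721) and the membrane protein gene Ms4a6d by 1.52 ± 0.18 (adjusted p = 0.00261). Rises in arrays 1 to 3 were larger than in arrays 4 to 6 for Clec4e (2.33 and 1.27), Fpr2 (2.22 and 0.92), Il6 (1.89 and 1.23), Marco (1.84 and 1.06) and Ms4a6d (1.82 and 1.10), and with the number set as a block the differences lay between 1.49 (Marco) and 1.86 (Clec4e). The fatty acid carrier Fabp5 went from 8.38 ± 0.11 to 9.39 ± 0.19, a 2.02-fold rise with the smallest adjusted p of the named genes (0.00026), which all 4 of its probesets showed. The oxysterol receptor Nr1h3 rose 2.13-fold and lipoprotein lipase, Lpl, 2.06-fold. The other probeset of Lpl, a dim one at 3.95, gave 0.22 (adjusted p = 0.574 over all probesets), and the mean of both gave 0.63 (adjusted p = 0.0434). Mmp14, a membrane-bound metalloproteinase, rose 2.45-fold, from 7.78 ± 0.23 to 9.07 ± 0.29.

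The other large rises were the carbonic anhydrase Car13 and the stress-response gene Nupr1 (both 1.24), the guanine deaminase Gda (1.24), the VEGF receptor Kdr (1.09), the lipopolysaccharide-inactivating enzyme Aoah (1.05) and the transcription factor Tfec (1.03). All 5 exposed arrays lay above all naive arrays for 14 of the 15 genes, and 4 did for Tfec. With the number set as a block, all 15 passed, with differences from 1.00 for Tfec and 0.998 for Fabp5 to 1.86 for Clec4e. With the characteristic's replicate number as a block, Gda (adjusted p = 0.0575), Kdr (0.0501), Lpl (0.0621) and Tfec (0.0631) did not pass. Kdr and Lpl depended on single arrays: Kdr failed in 3 of the fits with 1 array left out, at most at an adjusted p of 0.0615 without naive array 3, and Lpl in 4, at most at 0.0734 without exposed array 2. With the red pulp macrophage marker mean as a covariate, Clec4e (1.66, adjusted p = 0.0633), Kdr (0.81, adjusted p = 0.123), Lpl (0.61, adjusted p = 0.0557) and Tfec (0.73, adjusted p = 0.0678) no longer passed.

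After Il1r2, the metalloproteinases Mmp9 and Mmp12 were among the largest falls. They fell by 1.36 ± 0.25 (SE; adjusted p = 0.0180) and by 1.01 ± 0.16 (adjusted p = 0.0105). The C-type lectin Cd209a, a marker of type 2 conventional dendritic cells, fell by 1.02 ± 0.13 (adjusted p = 0.00345), from 11.25 ± 0.14 to 10.23 ± 0.35, though its other probeset gave -0.44 (adjusted p = 0.471 over all probesets). Its relative Cd209b fell by 0.82, and the inhibitory surface protein gene Cd101 fell by 1.08. Il1r2 gave -1.84 in arrays 1 to 3 and -1.76 in arrays 4 to 6, and -1.81 with the number set as a block. Cd209a gave -1.03, -1.02 and -1.02 in the same order, and Mmp9 gave -1.57, -0.98 and -1.31.

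Further falls were those of the drug efflux pump Abcb1a (-0.79), the lipid transporter Abca9 (-0.85), the sodium-potassium-chloride carrier Slc12a2 (-0.74) and the calcium channel subunit Cacna1e (-0.75). The cytochrome P450 gene Cyp4f37 (-1.23), the kinase gene Stk38l (-0.86), the adhesion receptor Adgrl3 (-0.76, and -0.11 at its other probeset), the sciellin gene Scel (-0.74) and the CD30 ligand Tnfsf8 (-0.72) completed the 15. Of the 30 largest rises and falls, 24 passed with every single array left out. Tnfsf8 failed in 10 of these 11 fits, at most at an adjusted p of 0.107 without exposed array 2, Cacna1e in 7 (0.0688 without naive 3), Cyp4f37 in 4 (0.0718 without exposed 2) and Abca9 in 3 (0.0642 without exposed 2). With the red pulp macrophage marker mean as a covariate 9 of the 15 falls missed the threshold: Il1r2 (-1.80, adjusted p = 0.0518), Mmp9 (-1.01, 0.0878), Mmp12 (-0.79, 0.0502), Cyp4f37 (-0.85, 0.121), Cd209b (-0.73, 0.0754), Adgrl3 (-0.67, 0.0636), Cacna1e (-0.71, 0.104), Scel (-0.64, 0.0909) and Tnfsf8 (-0.48, 0.190). With the characteristic's replicate number as a block Mmp12 (adjusted p = 0.0525), Cacna1e (0.0628) and Scel (0.0662) did not pass, and with the title's number Cacna1e (0.0548) did not.

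C/EBPβ, the transcription factor that the design is built on, was examined next. The study's description reports that it went down in dendritic cells exposed to lymphoma cells; in these arrays the Cebpb transcript pointed the other way and did not pass the test. The description does not say whether transcript or protein was measured there, nor how the cells were exposed. Cebpb (probeset 17379938) was measured at 6.95 ± 0.18 (SD, n = 6) in naive and 7.32 ± 0.42 (SD, n = 5) in exposed cells, a difference of 0.37 ± 0.16 (SE; 95% limits 0.02 to 0.72), or 1.29-fold, with an adjusted p of 0.366. By an exact permutation test, two-sided over 462 splits, p was 0.0931. Of the 5 exposed arrays, 3 lay above all naive arrays. The difference was 0.52 within arrays 1 to 3 and 0.07 within arrays 4 to 6, and 0.32 with the number set as a block (adjusted p = 0.0852). No single array left out made it pass.

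The rest of the family also stayed below the threshold. Cebpa differed by 0.23 ± 0.06 (adjusted p = 0.107), with 4 of 5 exposed arrays above all naive arrays, and passed only without exposed array 4, at 0.28 (adjusted p = 0.0418). The differences of Cebpd (-0.10), Cebpe (0.07), Cebpg (-0.02) and Ddit3 (-0.02) were small. Of the 6 measured C/EBP genes, 0 passed over all genes and 1 rose when adjusted over the list alone, and the list did not shift (mean 0.09, camera adjusted p = 0.370). Cebpz was not analysed here.

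**Figure D2:**
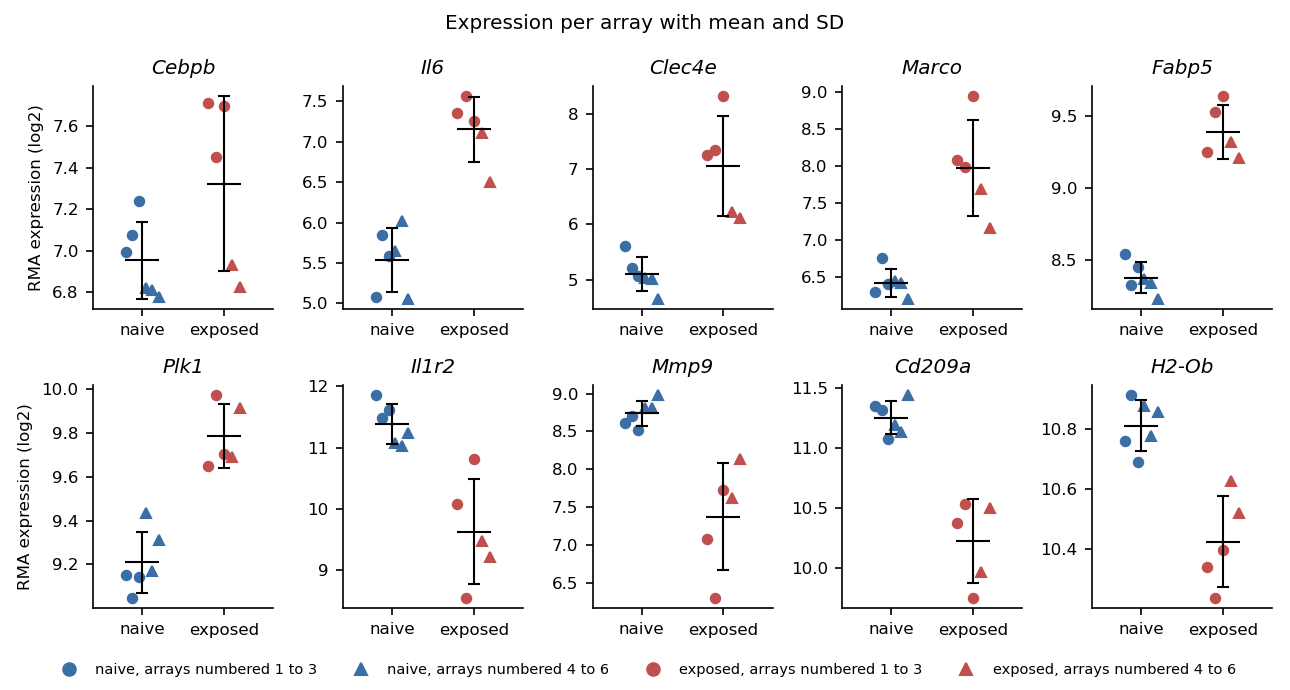
Log2 expression of 10 named genes on each array, with circles for arrays numbered 1 to 3, triangles for arrays numbered 4 to 6 and black marks for group mean ± SD. Il6 and Fabp5 are higher on all 5 exposed arrays than on any naive array and Il1r2 is lower on all 5, while for Cebpb 3 exposed arrays lie above all naive arrays.

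Cell division genes were higher in exposed cells. All 34 measured cell cycle genes had positive differences; 10 rose over all genes, 26 rose adjusted over the list alone, and none fell. The mitotic kinase Plk1 rose from 9.21 ± 0.14 (SD, n = 6) to 9.79 ± 0.15 (SD, n = 5), the anaphase activator Cdc20 from 8.35 ± 0.14 to 8.93 ± 0.13, both 1.49-fold, and the checkpoint kinase Bub1 rose 1.43-fold. The list's level went from 8.84 ± 0.11 to 9.19 ± 0.18, with 4 of 5 exposed arrays above all naive arrays (camera adjusted p = 2.48e-26; adjusted p = 0.385 with an estimated correlation; exact permutation p = 0.00433). It was 0.37 higher in arrays 1 to 3, 0.36 in arrays 4 to 6 and 0.37 with the number set as a block. Bub1 failed in 8 of the fits with 1 array left out, at most at an adjusted p of 0.0977 without exposed array 2.

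Smaller shifts appeared in sets of growth and protein turnover. Histone genes were 0.11 higher on average (26 of 34 positive, camera adjusted p = 0.00248; adjusted p = 0.451 with an estimated correlation): none passed over all genes, 6 rose adjusted over the list alone, and the linker histone gene H1f5 had the largest difference, 0.48 (adjusted p = 0.122), which passed with the number set as a block (0.52, adjusted p = 0.0137). Proteasome genes shifted up by 0.10, with 38 of 39 positive and 0 past the threshold over all genes or over the list alone (camera adjusted p = 2.14e-07; adjusted p = 0.451 with an estimated correlation). The largest difference in that symbol family was Psmc3ip (0.29, adjusted p = 0.396), which encodes a recombination factor and not a proteasome subunit. Complex I genes were 0.06 higher (36 of 42 positive, camera adjusted p = 0.00374; adjusted p = 0.510 with an estimated correlation), with 0 past the threshold either way, and the largest difference, -0.21 in Ndufaf7 (adjusted p = 0.227), belonged to an assembly factor. Within arrays 1 to 3 and 4 to 6 the means were 0.07 and 0.17 for histones, 0.13 and 0.07 for the proteasome and 0.09 and 0.03 for complex I. Histones did not pass in arrays 1 to 3 alone (adjusted p = 0.103), nor complex I in arrays 4 to 6 alone (adjusted p = 0.424).

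Myc target and ribosome biogenesis genes were 0.07 higher (22 of 25 positive, camera adjusted p = 0.0316; adjusted p = 0.575 with an estimated correlation; exact permutation p = 0.206), and none passed over all genes or over the list alone. The spermidine synthase gene Srm led with 0.30 (adjusted p = 0.176). This shift was lost without naive array 1 (0.05, adjusted p = 0.124), naive 2 (0.06, adjusted p = 0.0990), exposed 3 (0.05, adjusted p = 0.173) or exposed 6 (0.04, adjusted p = 0.265). It was also lost with only the 14787 brightest genes kept (adjusted p = 0.0726) and with the mean of all probesets of a gene (adjusted p = 0.0575). The 86 ribosomal protein genes stayed level (mean -0.002, camera adjusted p = 0.555, 0 passing either way); their largest difference was in a pseudogene, Rps15a-ps6 (-0.46, adjusted p = 0.491).

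Inflammatory genes shifted upward together. Of 25 measured cytokine and NF-kB target genes, 21 were higher in exposed cells. Il6, the interleukin 12 subunit Il12b (0.81, adjusted p = 0.0300) and the interleukin 1 receptor antagonist Il1rn (0.61, adjusted p = 0.0291) rose over all genes, 12 rose adjusted over the list alone, and none fell. The list went from 8.63 ± 0.08 (SD, n = 6) to 8.97 ± 0.19 (SD, n = 5), a mean difference of 0.34 (camera adjusted p = 8.98e-09; adjusted p = 0.385 with an estimated correlation; exact permutation p = 0.00433), with 4 of 5 exposed arrays above all naive arrays. It was 0.45 in arrays 1 to 3 and 0.18 in arrays 4 to 6. Il12b failed in 8 fits with 1 array left out, at most at an adjusted p of 0.0750 without naive 3, and Il1rn in 7, at most at 0.0717 without naive 6.

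Dendritic cell maturation genes rose as a list by 0.18 (camera adjusted p = 2.72e-05; adjusted p = 0.385 with an estimated correlation; exact permutation p = 0.0108). Of 22 members 6 rose and none fell over all genes, and 8 rose and 2 fell adjusted over the list alone. The cytokine signalling inhibitor Socs2 rose 1.78-fold, from 8.41 ± 0.27 to 9.24 ± 0.21, though its other probeset gave 0.23 (adjusted p = 0.1497 over all probesets), and the annexin gene Anxa3 1.45-fold, from 9.69 ± 0.17 to 10.23 ± 0.13; Il12b belongs here too. The list was 0.21 higher in arrays 1 to 3 and 0.14 in arrays 4 to 6.

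Inhibitory and checkpoint genes did not pass as a list (mean 0.14, camera adjusted p = 0.0877). Of 25 members 3 rose over all genes, and 5 rose and 2 fell adjusted over the list alone. The feedback inhibitor Socs3 rose 1.78-fold, from 7.15 ± 0.14 to 7.98 ± 0.38, the galectin Lgals1 rose by 0.51 and the inhibitory receptor Lilrb4a by 0.49. Lgals1 failed in 2 fits with 1 array left out (at most 0.0528, without naive 6) and Lilrb4a in 6 (at most 0.0695, without exposed 2). The list passed without naive array 2 (0.16, adjusted p = 0.0469) or exposed array 6 (0.18, adjusted p = 0.0173), and with a shift to a common 75th percentile (0.10, adjusted p = 0.0361). It also passed in arrays 1 to 3 alone (0.21, adjusted p = 0.0160) and not in arrays 4 to 6, where it was 0.04.

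Transcripts of the MHC class II presentation genes were slightly lower as a list. The 13 measured genes had a mean difference of -0.07, at 11.62 ± 0.03 (SD, n = 6) and 11.55 ± 0.04 (SD, n = 5), and 3 of them were positive (camera adjusted p = 0.00167; adjusted p = 0.385 with an estimated correlation; exact permutation p = 0.0130). H2-Ob and H2-Oa, the subunits of the DO protein that restrains peptide loading, fell by 0.39 and 0.26 on the log2 scale, with all 5 exposed arrays below all naive arrays for each. No member rose over all genes, and adjusted over the list alone 3 fell and none rose. The mean was -0.07 in arrays 1 to 3 and -0.06 in arrays 4 to 6, where it did not pass alone (adjusted p = 0.0763). The 17 MHC class I presentation genes did not shift (mean 0.02, or -0.02 with a shift to a common 75th percentile; camera adjusted p = 0.689), with 0 passing either way and the proteasome activator Psme2 showing the largest difference (0.18, adjusted p = 0.360).

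Markers of type 2 conventional dendritic cells were lower as a list and mixed by member. Of 17 members, Cd209a, the lectin Clec4a4 (-0.43, adjusted p = 0.0250) and the surface receptor Cd7 (-0.37, adjusted p = 0.0237) fell and the fractalkine receptor Cx3cr1 rose (0.46, adjusted p = 0.00866). Adjusted over the list alone 3 rose and 6 fell. The list went from 9.57 ± 0.05 to 9.46 ± 0.06, a mean of -0.12 (camera adjusted p = 0.0259; adjusted p = 0.385 with an estimated correlation; exact permutation p = 0.0152), with -0.11 in arrays 1 to 3 and -0.12 in arrays 4 to 6 (adjusted p = 0.0513 and 0.0763 within each set alone). The shift missed the threshold without exposed array 4 (-0.11, adjusted p = 0.0549), after another quantile normalisation (-0.11, adjusted p = 0.0589) and with the red pulp macrophage marker mean as a covariate (-0.11, adjusted p = 0.0645). Clec4a4 and Cd7 each failed in 7 of 11 fits with 1 array left out, at most at 0.0631 without exposed 2 and 0.0577 without naive 6.

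The other dendritic cell sets did not pass over all arrays without a block. The 18 markers of type 1 conventional dendritic cells had 0 changed members and a mean of 0.03, or -0.01 with a shift to a common 75th percentile (camera adjusted p = 0.543), led by the endocytic receptor Ly75 (0.20, adjusted p = 0.396). Of 14 plasmacytoid markers Smim5 rose (0.39) and Cd300c fell (-0.41), over all genes and adjusted over the list alone (list mean 0.16, camera adjusted p = 0.166). The plasmacytoid list passed with the replicate number as a block, at 0.15 with the title's number (adjusted p = 0.0180) and with the characteristic's (adjusted p = 0.0308), and within arrays 1 to 3 alone (0.22, adjusted p = 0.0380), but not within arrays 4 to 6 (0.05). Its changed members lost their calls under the same blocks, Smim5 with the title's number (adjusted p = 0.0617) and Cd300c with either (0.0502 and 0.0685). Smim5 failed in 6 and Cd300c in 8 fits with 1 array left out, at most at 0.0898 and 0.0977, both without exposed array 2. The 14 migration and positioning receptors had 0 changed members over all genes and 1 fall adjusted over the list alone (mean 0.05, camera adjusted p = 0.741). Their largest difference, in Ccr1 (0.32, adjusted p = 0.238), lay at a level below that of the brighter olfactory receptors in both groups.

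Pattern recognition receptors split. Clec4e rose, while the beta-glucan receptor Clec7a (-0.53, adjusted p = 0.0374), the inflammasome sensor Nlrp3 (-0.44, adjusted p = 0.0118) and the peptidoglycan sensor Nod2 (-0.38, adjusted p = 0.0196; -0.21 at its other probeset) fell. Adjusted over the list alone 2 of 22 rose and 6 fell. The list's mean was 0.06, its median -0.04 and camera's direction down (adjusted p = 0.128), so mean and test differed in sign; without naive array 1 camera passed (adjusted p = 0.0459). Clec7a failed in 9 fits with 1 array left out, at most at an adjusted p of 0.111 without exposed 2, and Nod2 in 1 (0.0642 without exposed 2). Within arrays 1 to 3 and 4 to 6 Clec7a gave -0.51 and -0.62 and Nlrp3 -0.37 and -0.52.

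Red pulp macrophage markers were higher in exposed cells and uneven across arrays. Of 15 members 14 were positive. Marco rose over all genes, 6 rose adjusted over the list alone, and none fell. Among naive arrays Marco followed the other members little (slope 0.29), so its rise does not stand for the list. The list went from 8.15 ± 0.34 (SD, n = 6) to 8.91 ± 0.82 (SD, n = 5), a mean of 0.75 (camera adjusted p = 4.48e-06; adjusted p = 0.451 with an estimated correlation; exact permutation p = 0.0498). Exposed arrays 1 and 2 stood at 10.19 and 9.25, the other exposed arrays between 8.20 and 8.55 and the naive arrays between 7.64 and 8.67. The mean was 1.12 in arrays 1 to 3 and 0.17 in arrays 4 to 6, where it did not pass alone (adjusted p = 0.138), and 0.43 without exposed array 1 (adjusted p = 0.00282).

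Other sets had extreme values on the same arrays. Lysosome and phagocytosis genes shifted up by 0.20 (18 of 24 positive, camera adjusted p = 0.00146; adjusted p = 0.488 with an estimated correlation), at 10.49 and 10.22 on exposed arrays 1 and 2 against 9.78 to 10.05 on naive arrays. The membrane protein gene Lamp1 (0.44, adjusted p = 0.0180) and Lpl, a secreted lipase and no lysosomal protein, rose over all genes, and 4 rose adjusted over the list alone. The lysosome shift was 0.31 in arrays 1 to 3 and 0.03 in arrays 4 to 6, was lost without exposed array 1 (0.11, adjusted p = 0.114) and with the red pulp macrophage marker mean as a covariate (-0.021, adjusted p = 0.543), and Lamp1 failed without exposed array 2 (adjusted p = 0.0577). Type I interferon response genes did not shift (mean 0.07, camera adjusted p = 0.370): the chemokine Cxcl10 was the 1 of 31 members to rise (0.80, adjusted p = 0.0300), and 2 rose adjusted over the list alone. That list stood at 8.83 and 8.91 on exposed arrays 1 and 2 and between 8.39 and 8.55 on the other exposed arrays. It passed upward without exposed array 3 (0.13, adjusted p = 0.00546) and in arrays 1 to 3 alone (0.19, adjusted p = 0.00717). It was lower, at -0.08, in arrays 4 to 6 alone (adjusted p = 0.00138) and, at -0.064, with the macrophage covariate (adjusted p = 0.0431). These p-values came from camera with the preset correlation of 0.01, while the list's estimated correlation was 0.48. Over all arrays its exact permutation p was 0.487, and arrays 4 to 6 hold only 3 naive and 2 exposed arrays. The values thus do not establish a reversal. Cxcl10 failed in 7 fits with 1 array left out, at most at 0.0896 without exposed 2. Cebpb stood at 7.71 and 7.45 on exposed arrays 1 and 2 and at 7.70 on exposed array 3.

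Small nucleolar RNAs were lowest on exposed array 1, at 8.17 against 8.54 to 9.03 on naive arrays. The 73 genes shifted down by 0.12 (17 positive, camera adjusted p = 0.000514; adjusted p = 0.596 with an estimated correlation; exact permutation p = 0.470), 0 passed over all genes or over the list alone, and Snora73b had the largest difference (-0.52, adjusted p = 0.435). Without exposed array 1 the mean was 0.0033 and camera no longer passed, and it was -0.21 in arrays 1 to 3 and 0.02 in arrays 4 to 6. With the red pulp macrophage marker mean as a covariate the list passed in the opposite direction (0.14, adjusted p = 0.00278). The 472 microRNA genes did not shift (mean -0.01, camera adjusted p = 0.342, 0 passing either way) but passed downward in arrays 1 to 3 alone (-0.04, adjusted p = 0.0423); Mir27a led with 0.69 (adjusted p = 0.108) and passed without exposed array 6 (0.85, adjusted p = 0.0274).

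Immunoglobulin segment genes were higher in exposed cells by 0.45, with all 21 positive (camera adjusted p = 5.08e-05; adjusted p = 0.451 with an estimated correlation; exact permutation p = 0.108). Ighg3, an immunoglobulin heavy chain constant gene, rose from 6.17 ± 0.16 (SD, n = 6) to 7.07 ± 0.41 (SD, n = 5) and was the 1 member to pass, over all genes and adjusted over the list alone; its other probeset gave -0.01. Naive array 1, at 7.16, stood above 3 of the 5 exposed arrays and naive array 3, at 7.21, above 4. The mean was 0.31 in arrays 1 to 3 and 0.49 in arrays 4 to 6. The symbol family also takes in Ighmbp2, a helicase gene.

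B cell markers themselves did not shift (mean 0.04, camera adjusted p = 0.920). The inhibitory receptor Cd22 fell (-0.54, adjusted p = 0.0238), 1 of 18 members to pass, and 3 rose and 3 fell adjusted over the list alone. The mean was 0.10 in arrays 1 to 3 and -0.07 in arrays 4 to 6. Cd22 failed in 6 fits with 1 array left out, at most at an adjusted p of 0.0743 without exposed 2. Of 11 B precursor markers the interleukin 7 receptor gene Il7r rose (0.58, adjusted p = 0.0311) and 2 rose adjusted over the list alone (mean 0.12, camera adjusted p = 0.0654). Il7r failed in 7 such fits, at most at 0.0778 without naive 5. The precursor list passed after another quantile normalisation (adjusted p = 0.0490), with only the 14787 brightest genes kept (0.22, adjusted p = 0.0420) and without naive 1 (0.13, adjusted p = 0.0473), naive 3 (0.13, adjusted p = 0.0409), exposed 3 (0.14, adjusted p = 0.0407) or exposed 6 (0.15, adjusted p = 0.0303).

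T and NK cell markers were mixed. Of 12 NK cell markers the activating receptor Ncr1 rose (0.46, adjusted p = 0.0289) and Klrd1, a CD94 gene, fell (-0.52, adjusted p = 0.0452); adjusted over the list alone 5 rose and 1 fell (mean 0.11, camera adjusted p = 0.0513). Ncr1 failed in 8 and Klrd1 in 10 fits with 1 array left out, at most at 0.0822 without exposed 2 and 0.103 without naive 6. The NK list passed with each rescaling (adjusted p = 0.0381 after median centring, 0.0271 after quantile normalisation and 0.0361 at a common 75th percentile) and without naive 1 (0.13, adjusted p = 0.0205), naive 2 (0.12, adjusted p = 0.0429), exposed 3 (0.12, adjusted p = 0.0441) or exposed 4 (0.14, adjusted p = 0.00744). The 11 T cell markers had 0 changed members over all genes, with 1 rise and 1 fall adjusted over the list alone (mean 0.07, camera adjusted p = 0.342), led by the dim Cd3g (0.34, adjusted p = 0.169). The 9 T cell receptor segments had 0 passing either way (mean 0.07, camera adjusted p = 0.379), led by Trav9d-3 (0.23).

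Among markers of other blood cells, lysozyme, Lyz2, rose by 0.50 (adjusted p = 0.0355) as 1 of 16 monocyte markers, over all genes and adjusted over the list alone (mean 0.09, camera adjusted p = 0.198), and failed in 10 fits with 1 array left out, at most at 0.0940 without exposed 3. Of 14 neutrophil markers Mmp9, which dendritic cells express too, fell over all genes, and 1 rose and 1 fell adjusted over the list alone (mean -0.04, median 0.03, camera upward at adjusted p = 0.920, so mean and test differed in sign). The carbonic anhydrase Car2 rose 1.73-fold, from 7.82 ± 0.26 to 8.61 ± 0.14, as 1 of 8 erythroid markers by either adjustment (mean 0.18, camera adjusted p = 0.0654). That list passed after quantile normalisation (adjusted p = 0.0490), at a common 75th percentile (adjusted p = 0.0361) and without naive 4 (0.21, adjusted p = 0.0409), exposed 3 (0.19, adjusted p = 0.0491) or exposed 4 (0.21, adjusted p = 0.0390), and in arrays 1 to 3 alone (0.27, adjusted p = 0.0223) against 0.06 in arrays 4 to 6. The 9 platelet markers had 0 passing either way (mean -0.01, camera adjusted p = 0.458), led by the dim Gp5 (-0.14, adjusted p = 0.573).

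Interferon gamma, stress and metabolic genes did not shift as lists. The 17 interferon gamma response genes had 0 changed members, with 2 rises and 1 fall adjusted over the list alone (mean 0.10, camera adjusted p = 0.458), led by the GTPase Iigp1 (0.64, adjusted p = 0.163), which passed without exposed array 3 (0.82, adjusted p = 0.0474). The 17 unfolded protein and integrated stress response genes had 0 changed members, with 2 rises and 1 fall adjusted over the list alone (mean 0.04, camera adjusted p = 0.166). The stress sensor Sesn2 led with -0.34 (adjusted p = 0.114) and passed with the number set as a block (-0.32, adjusted p = 0.0489). Of 21 glycolysis and hypoxia genes the glycolytic regulator Pfkfb3 rose (0.28, adjusted p = 0.0400), and 5 rose and 1 fell adjusted over the list alone (mean 0.02, or -0.01 at a common 75th percentile, camera adjusted p = 0.174). Pfkfb3 failed in 9 fits with 1 array left out, at most at 0.102 without exposed 3.

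The 15 cholesterol synthesis genes had 0 passing either way (mean 0.05, camera adjusted p = 0.402), led by Mvd (0.24, adjusted p = 0.246), and shifted up without exposed array 2 (0.11, adjusted p = 0.00784) and with the red pulp macrophage marker mean as a covariate (0.14, adjusted p = 0.00919). Of 24 immediate early and heat shock genes the transcription factor Klf2 rose (0.66, adjusted p = 0.0310), and 4 rose adjusted over the list alone (mean 0.11, camera adjusted p = 0.149). The immediate early list was 0.23 in arrays 1 to 3 (adjusted p = 0.00150 alone) and -0.08 in arrays 4 to 6 (adjusted p = 0.0237 alone). It passed without naive 2 (0.16, adjusted p = 0.00560), exposed 2 (0.13, adjusted p = 0.0323) or exposed 6 (0.18, adjusted p = 0.00203). These p-values too used the preset correlation, while the list's estimated correlation was 0.54. Its exact permutation p over all arrays was 0.355, so a reversal is not established here either. Klf2 failed in 8 fits with 1 array left out, at most at 0.0977 without exposed 2. The 1105 olfactory receptors stayed at 3.64 in both groups (mean 0.01, camera downward at adjusted p = 0.785); Olfr331 fell by 1.08 (adjusted p = 0.0264) over all genes, while adjusted over the list alone 0 passed, and it failed in 6 such fits, at most at 0.0822 without exposed 2.

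Across the 38 sets camera called 13 shifted, 10 up and 3 down, the same 13 with the number set as a block. With an estimated correlation 0 passed (smallest adjusted p = 0.385), with 4 sets at an unadjusted p under 0.05, and fry called 0, with 12 at an unadjusted p under 0.05. Exact permutation gave an unadjusted p under 0.05 for 11 sets, 7 of them among the 13, and 0 after adjustment.

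**Figure D3:**
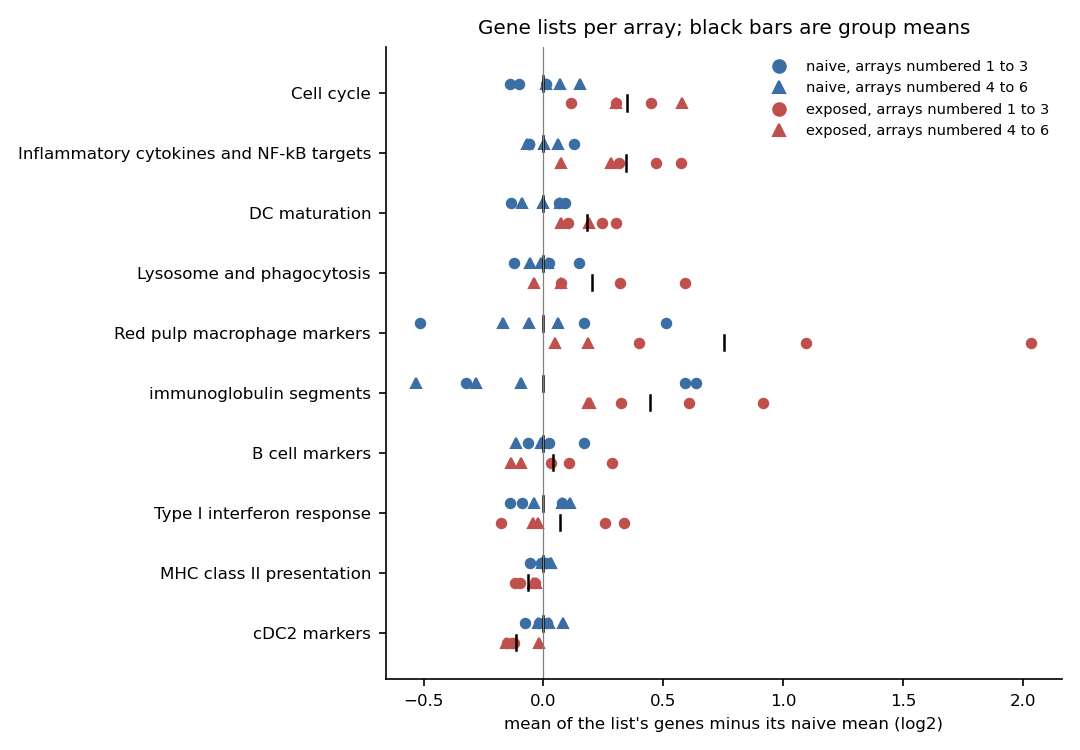
Mean of each of 10 gene lists on each array minus the list's naive mean (log2), with circles for arrays numbered 1 to 3, triangles for arrays numbered 4 to 6 and black bars for group means. The cell cycle list is higher on 4 of 5 exposed arrays than on any naive array, while the red pulp macrophage list stands apart on exposed arrays 1 and 2.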

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

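The number-set block and the tests of the macrophage markers and of the cell cycle genes in this part were chosen only after those results had been seen, as was the use of the macrophage covariate to weigh the changed genes, while the covariate fit itself and the counts over other splits of the arrays were planned.

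Single arrays lay far from the rest of their group for 5 named genes. Fpr2 was 4.90 on naive array 3 against 5.53 to 5.79 on the other naive arrays, Abcb1a was 9.92 on naive array 2 against 9.57 to 9.66, and Nlrp3 was 8.997 on naive array 1 against 9.16 to 9.25. Gda was 7.70 on exposed array 3 against 6.67 to 6.79 on the other exposed arrays. Cebpe was 5.42 on naive array 6 against 5.66 to 5.71, and 5.91 on exposed array 1 against 5.64 to 5.66. Among gene lists, the type 2 dendritic cell markers stood at 9.55 on exposed array 6 against 9.42 to 9.45, the erythroid markers at 6.12 on naive array 4 against 5.94 to 5.99, and the glycolysis and hypoxia genes at 8.96 on exposed array 3 against 8.87 to 8.89. These are 9 of 254 groups tested, and at 1 in 20 chance gives 12.7. Outside the gene-level comparison, 24 of 12292 probesets passed the same threshold when every probeset was tested, 16 higher and 8 lower: 7 name several genes, 14 have no gene name and 3 are further probesets of a named gene.

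Over 100 splits of the 11 arrays into 6 and 5, the real one included, 1 gave as many changed genes as the real 316 (highest other 1). For changes of at least 2-fold, 1 gave as many as the real 22 (highest other 0). Both counts thus stood above all other splits drawn, which took no account of the number sets. For the number of shifted gene lists chance cannot be excluded, since 18 of the 100 splits shifted at least the real 13. The highest other split shifted 18 lists and the median of the other splits was 9. The split that follows the number sets was not among those drawn. It called 413 genes, more than the real one, 1 of them by at least 2-fold, and 10 lists, which points to a structure of the arrays besides the groups. The count of changed genes alone therefore does not exclude chance. With that structure as a block the groups differed in 617 genes.

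The 195 genes that were higher in exposed arrays had a median log2 difference of 0.46, with a median SE of 0.0899. A larger share of red pulp macrophages was tested with their marker mean as a covariate. The median became 0.45, a ratio of 0.978 with a median SE of 0.1003. All 195 genes stayed positive and 85 still passed. Genes that follow these uneven markers vary within the exposed group and seldom pass, so choosing changed genes favours such a ratio. The differences of these 195 genes thus kept their size beside the covariate. Because of how the genes were chosen, this cannot decide whether macrophages were the cause, and it says nothing of other genes. Single genes such as Lpl, which went from 1.04 to 0.61 with the covariate, may partly follow the macrophage markers. A difference between the number sets was tested with a block, under which 100% of the 195 genes passed. The sets are nearly balanced between the groups, so the block could hardly change the differences and this pass rate adds little. More macrophages, an effect of lymphoma on dendritic cells, a different mix of their subsets and unrecorded differences between the mice stay open.

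Red pulp macrophage markers were 0.75 higher in exposed cells, mostly through exposed arrays 1 and 2, although the sort for CD11c and MHC class II should remove most macrophages. If more such cells were present, the members that vary most with the others among naive arrays should differ most. Across the 15 members, which are genes and not independent replicates, r was 0.326 (one-sided permutation p = 0.116) and rho 0.393 (one-sided permutation p = 0.0744), and r was 0.279 without the 2 members of the most extreme slope. Cd5l and C1qa went with such cells, with slopes of 1.60 and 1.09 and differences of 1.89 and 0.95. Slc40a1 and Hmox1 had the steepest slopes, 2.49 and 1.65, but differed by only 0.71 and 0.43. Marco had a slope of 0.29 and a difference of 1.54. Adgre1 and Hmox1 went from 10.46 to 10.28 and from 10.15 to 10.58. More macrophages and a change of these genes within dendritic cells cannot be told apart with 6 naive arrays and 15 genes, all above the dim level in naive cells already.

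Cell cycle genes were 0.35 higher in exposed cells. For lymphoma B cells among the sorted cells the B-lineage lists disagreed: in arrays 4 to 6 the B cell list differed by -0.072 and the B precursor list by 0.14, beside 0.36 for the cell cycle list, and over all arrays exact permutation gave p = 0.00649 for the precursor list and 0.00433 for the cell cycle list (both 0.0720 after adjustment). Within arrays 4 to 6 the precursor value rested on exposed array 4 (5.64). Over all arrays 4 of 5 exposed arrays lay above all naive arrays for the precursor list, which was 0.11 higher in arrays 1 to 3. Only 4 of its 11 members lay above the dim level in naive cells. Exposed 6, with the highest cell cycle level of all arrays (9.42), stood at 5.43 for precursor and 7.37 for B cell markers. Both values lay within those of naive arrays 4 to 6, and a single array excludes nothing. With the number set as a block the cell cycle difference was 0.37. The sets are nearly balanced between the groups, so the block could hardly change it. In arrays 1 to 3 the B cell list was 0.10 higher and immunoglobulin segments were higher in both sets, so lymphoma cells stay open as a source, as do dividing dendritic cells, their precursors and other dividing cells, which were not tested.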

How the results depend on the processing

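The settings that treat the number set as a block or use each number set alone were chosen only after the arrays had been seen. The 316 changed genes became 182 with the characteristic's replicate number as a block (341 with the title's, under which naive array 5 has no partner), 489 with the B cell marker mean and 189 with the red pulp macrophage marker mean as a covariate, 617 with the number set as a block, 208 of all probesets when each was tested by itself, and 11 with treat against 1.2-fold. Arrays 1 to 3 alone gave 11 and arrays 4 to 6 alone 5, and for changes of at least 2-fold 7 and 3 in place of 22; fewer arrays were tested there. With single arrays left out the counts ran from 104 to 395 and, at 2-fold, from 16 to 38. The 13 list shifts became 0 with an estimated correlation and 0 with fry. Cebpb kept its sign in all alternatives run, between 0.07 and 0.52, and passed in none. With the macrophage covariate the type I interferon list became -0.064, the lysosome list -0.021 and the small nucleolar RNAs 0.14, the first and last passing in the opposite direction (adjusted p = 0.0431 and 0.00278), which by construction removes what follows those markers; a list whose own mean is the covariate gives no value. In arrays 4 to 6 alone the type I interferon list was -0.083, the immediate early list -0.078 and the small nucleolar RNAs 0.023. The cause of the other moves was not tested. Of the 62 changed named genes 34 missed the threshold with the macrophage covariate, 23 with the characteristic's and 9 with the title's replicate number as a block, and 35 passed with every single array left out. Testing every probeset by itself ended the call of 15 of them, eBayes without trend of 4, median centring of 3, and quantile normalisation and the common 75th percentile of 1 each. Precision is limited by 11 arrays, and Cd3g, Gp5 and Ccr1 lay below the dim level of 5.60 in both groups.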

Other observations

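The genes of the first paragraphs of this part were chosen after their values were seen, and so were the genes that led to the hypotheses, whose lists and tests were written before the values of those lists were seen.

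Several further changed genes encode ligands or receptors, which no list tested as a group. The TNF family ligands Lta and Tnfsf15 rose from 6.88 ± 0.09 to 7.86 ± 0.22 and from 7.01 ± 0.22 to 7.86 ± 0.30 (SD, n = 6 and 5), and the chemokines Ccl2, which draws monocytes, and Xcl1, the ligand of the receptor on type 1 conventional dendritic cells, rose by 0.99 and 0.89. Il23r, part of the interleukin 23 receptor, rose by 0.81, Il2ra by 0.55 and the Notch ligand Dll4 by 0.58. Among receptors for extracellular nucleotides P2ry13 (0.97), P2ry12 (0.65) and P2ry2 (0.40) rose, while P2ry10, which shares their name, fell (-0.30). The scavenger receptor Msr1 (0.90) and the fatty acid carrier Fabp4 (0.91) rose beside Fabp5, and complement factor B, Cfb, rose by 0.89.

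Among single genes that no list tested as a group, Nlrp1b fell by 0.60, the inflammasome gene Nlrc4 by 0.39 and the pseudogene Nlrp1c-ps by 0.70, beside Nlrp3. The transcription factors Stat4 (-0.64), Ahr (-0.45), Mef2c (-0.39), Satb1 (-0.29) and Bcl11a (-0.24) were lower, with all 5 exposed arrays below all naive arrays for each, while others, such as Tfec and Klf2, rose. On the rising side also stood the mitotic regulator Foxm1 (0.50, adjusted p = 0.00866) and the cytokinesis genes Kif4 (0.52), Prc1 (0.53) and Anln (0.53), which are not in the cell cycle list. Irak3, a brake on Toll-like receptor signalling, rose by 0.81, and Txnip, a brake on glucose uptake, fell by 0.49.

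A first hypothesis was that LXR, the receptor encoded by the higher Nr1h3, was more active. Its 10 measured target genes were all positive, with a mean of 0.151 (95% limits -0.12 to 0.42; camera adjusted p = 0.0493; adjusted p = 0.532 with an estimated correlation; exact permutation p = 0.247), and 0 passed singly. They were 0.29 in arrays 1 to 3 and -0.05 in arrays 4 to 6, so the values leave open whether LXR may be more active.

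A lower glucocorticoid response could explain the falls of Il1r2 and Txnip. The 12 measured glucocorticoid-induced genes had a mean of -0.0632 (95% limits -0.25 to 0.13; exact permutation p = 0.439), 6 positive and 6 negative, at 0.03 in arrays 1 to 3 and -0.20 in arrays 4 to 6, which decides nothing.

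Higher Fas (0.68) and Dram1 (0.92), both p53 targets, raised p53 activity as a candidate explanation. The 13 measured p53 targets other than these had a mean of 0.0108 with an upper 95% limit of 0.0949, a median of -0.0007 and camera downward, at 0.04 in arrays 1 to 3 and -0.03 in arrays 4 to 6, and this argues against a general rise of more than 0.1.

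Higher Il6 and Socs3 raised signalling through STAT3 as a candidate. The 13 measured STAT3 targets had a mean of 0.083 (95% limits -0.01 to 0.18; exact permutation p = 0.0736), at 0.14 in arrays 1 to 3 and -0.01 in arrays 4 to 6, with 0 past the threshold over all genes and 2 adjusted over the list alone, so the question stays open.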
